A study of Homo sapiens with 3 samples.

How the data were processed

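ATAC-seq libraries were made from HL60 cells with the Active Motif ATAC-Seq Express kit, per the labels' protocols. There was 1 library for each of 3 groups: a control treated with the solvent DMSO, cells given 250 nM cytarabine (AraC) for 1 day (Day 1), and cells given the drug for 3 days and then kept without it for 9 days (Day 14). Groups were taken from the library names in the labels. Cells in G0/G1 were sorted by flow cytometry before the assay, per the labels' protocols.

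The deposited files hold whole-number read counts per region, with chromosome, start, end and count and no header line. Cutadapt, Bowtie2, MACS2, bedtools and the build hg38 are named, with no versions, per the submitters' processing notes. The role of each tool, the counting rule, any removal of duplicate or mitochondrial reads, any shift of read ends for the transposase and the library or libraries on which the regions were called are not given in the sources used here. If the regions came from some libraries only, sites open in another would be missing from all counts. The files list the same 114037 regions, of which 99.1% are 500 bp wide and the widest is 1954 bp. The 193 regions outside chromosomes 1 to 22 and X were left out, which removed 0.138% of counts in the control, 0.0839% in Day 1 and 0.106% in Day 14.

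Effective library sizes were total counts in the 113844 remaining regions times TMM factors from edgeR 4.0.16 in R 4.3.3. The factors were 0.951 for the control, 1.07 for Day 1 and 0.980 for Day 14. A log2 fold is the log2 ratio of normalised counts after adding a pseudocount of 1 scaled to library size, so it understates differences at low counts. Regions and promoters with a mean of at least 20 counts over the 3 libraries entered the comparisons, 102334 regions and 13248 genes in all. Starts are printed counted from 1.

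Gene positions came from a RefSeq gene table for assembly GRCh38.p14, which is the same build as hg38. That table has no strand, exons or introns, and no genome sequence was used here. The design had foreseen transcription start sites. In their place, a gene's promoter value is the summed count of regions within 1 kb of whichever annotated gene end had the higher mean count over the 3 libraries, for protein-coding genes. For 936 of the 13248 genes the other end reached at least 50% of that mean, and the side of the promoter is then uncertain; such genes are marked where their promoter is first named as having regions at both ends. A region can serve the promoters of neighbouring genes, and reads from near-identical gene copies cannot be told apart. Promoter regions are those used for any gene, other genic regions overlap a protein-coding gene, and the rest are intergenic.

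With 1 library per group there was no test between conditions, no replicate check and no p-value. Regions were counted by a 2-fold size rule, beside the count that counting error alone gives when the pooled counts of a pair of libraries are split at random by library size, over 100 draws. Exact (Clopper-Pearson) 95% intervals of a ratio are given with named items. Reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. At equal normalised counts, relative counting error is largest in the control, since its total count was 8091908 against 13717951 in Day 1 and 18607249 in Day 14.

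The 18 gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. A list's median log2 fold was set against 10000 random lists of the same size, drawn with replacement and matched on decile of mean promoter count. A list outside the central 95% of these is described as outside the matched range, which describes these libraries only. All 370 list entries matched the gene table, 2 of them through an older symbol. Named genes are the 10 highest and 10 lowest promoters per comparison with a mean of at least 50 counts, the 5 highest and 5 lowest regions over 5 kb from any annotated gene end with that mean, and the 2 to 4 members of each list with the largest absolute fold, of which fewer or none are printed for lists inside the matched range. CDKN1A in Day 14 vs control is printed beside its value in Day 1. Distal regions are named by the gene whose span holds them or, outside genes, by the nearest gene end.

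Alternatives were scaling to total counts, DESeq2 1.42.0 median-of-ratios size factors, ribosomal protein promoters set to a median of 0, and a lowess trend of log2 fold on mean log2 count (fraction 0.3) subtracted. Others were a pseudocount of 5, no count filter beyond a mean of 1, a mean of at least 50, and all regions whose gene end was nearest within 50 kb in place of promoters. Thinning all libraries to the control's size, counting regions over the whole gene, and the alternatives for region classes were added after the data were seen. Relative to the main scaling, the median region of Day 1 vs control moved by 0.17 with total counts and by 0.71 with ribosomal protein promoters. For Day 14 vs control the moves were 0.042 and 0.17, and for Day 14 vs Day 1 they were -0.13 and -0.57. Statistics used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with matplotlib 3.10.9 for plots.

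The methods were tested on simulated data, with Poisson counts drawn from pooled rates over 102334 regions and 200 regions changed per comparison. The 2-fold rule recovered 94.0% of regions changed 3-fold and 100% of those changed 5-fold for Day 1 vs control. The shares were 97.0% and 98.0% for Day 14 vs control, and 96.0% and 100% for Day 14 vs Day 1. Of unchanged regions, 0.935%, 0.726% and 0.156% passed the rule in the same order. Library sizes were taken as known in the simulation, and unchanged regions differed by counting error only. These shares leave out errors of scaling and other differences between libraries, so they do not carry over to the real regions. Among 200 unchanged lists of 12 genes, drawn from 13248 genes, 7.50%, 6.00% and 4.00% lay outside the matched range, and lists raised by 0.5 on the log2 scale lay above it in 100% of draws for each comparison. Simulated genes differed by counting error only. In the data, the matched range for Day 1 vs control reached 0.39 above its median for neutrophil markers and 0.55 for erythroid markers. The 100% therefore does not carry over to the real lists.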

Results

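Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in HL60 cells, a human promyeloblastic leukaemia line. The labels also give peripheral blood leukocytes as the tissue of these samples. Cells received cytarabine (AraC), a cytidine analogue used against acute myeloid leukaemia, or its solvent DMSO, and G0/G1 cells were sorted after Pyronin Y and Hoechst staining. The control, Day 1 and Day 14 groups held 1 library each. Day 1 cells had 1 day of drug, and Day 14 cells had 3 days of drug and 9 days without it, which add to 12 days; the label's name is kept. The day on which control cells were collected is not given in the sources used here. Total counts over 114037 regions were 8091908 in the control, 13717951 in Day 1 and 18607249 in Day 14, with median counts per region of 30, 63 and 73. Sample titles place the control and Day 1 on the same sequencing lane and Day 14 on another, so the lane and the Day 14 group cannot be told apart. No difference has a replicate check, and each interval is an exact 95% counting interval of a ratio of libraries.

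The series title concerns cytarabine resistance and rapid transcription dynamics, and the first comparison asks how accessibility after 1 day of drug differed from the control. Promoters of neutrophil, lymphoid, monocyte and granule genes were more accessible in Day 1 relative to promoters of similar count, and ribosomal protein promoters were less so. The 12 measured neutrophil maturation markers had a median log2 fold 0.60 above matched promoters, and 9 of them had intervals above the matched median and 0 below. Among them, ITGAM, the integrin alpha M chain with regions at both gene ends, had a log2 fold of 1.08 (0.57 to 1.65), the chemokine receptor gene CXCR2 of 0.98 (0.41 to 1.61) and the gelatinase gene MMP9 of 0.71 (0.15 to 1.32). Lymphoid markers, fixed as genes of another cell type, were 0.53 above matched promoters with 8 of 13 intervals above, led by the T cell kinase gene LCK at 1.5 (0.86 to 2.25), CD2 at 0.84 (-0.17 to 2.05) from 10 counts in the control, and the B cell receptor gene CD79A at 0.61. Monocyte and macrophage markers were 0.48 above, with 5 of 9 intervals above the matched median, but 0 of 9 excluded a fold of 0. CD86 at 0.40 (-0.29 to 1.16) and CYBB at 0.37 (-0.72 to 1.61), from 10 counts in the control, had the largest folds. Promyelocyte granule genes were 0.31 above, with 8 of 14 intervals above and 1 below. Against the control itself, that list had a median log2 fold of -0.11, with 3 intervals above 0 and 5 below. In that list the myeloperoxidase gene MPO was higher at 0.84 (0.38 to 1.33), as was MS4A3 at 0.64 (0.18 to 1.12), and the neutrophil elastase gene ELANE lower at -0.61 (-0.77 to -0.44). Ribosomal protein promoters had a difference of -0.16 from matched promoters, with 15 of 34 intervals below and 2 above, and RPS23 at -1.33 and RPL14 at -1.27 were the lowest.

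These 5 of 18 lists lay outside the matched range in Day 1 vs control, where chance gives 0.9. Counting all regions nearest to a gene end within 50 kb brought the lymphoid list to 0.26 and the granule list to 0.14, both inside the range, and subtracting the intensity trend brought the monocyte list inside it at 0.32.

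Genes that handle cytarabine differed in both directions, and the list as a whole stayed inside the matched range (difference -0.091, 5 of 20 intervals above and 8 below). The promoter of CDA, cytidine deaminase, which inactivates cytarabine, lies at the annotated gene on chromosome 1 from 20589097 to 20618903 (hg38). It had 33 counts in the control and 178 in Day 1, a log2 fold of 1.48 (0.95 to 2.08). Lower promoters were those of DCTD, deoxycytidylate deaminase, at -1.31 (-1.59 to -1.05), DUT, the dUTPase, at -1.31 (-1.55 to -1.07) and the efflux transporter gene ABCC4 at -1.16. The median of all promoters in this comparison was -0.48. Interferon response genes also split: IFIT2 at 1.57 (0.80 to 2.5), OASL at 1.5 (1.00 to 2.07), OAS1 at 0.94 and OAS2 at 0.89 were higher. The list, with 10 of 19 intervals above and 3 below, was 0.28 above matched promoters and inside their range. It lay outside at 0.36 after the intensity trend was subtracted, at 0.41 with a mean of at least 50 and at 0.38 with no count filter.

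Among DNA damage and p53 target genes, CDKN1A, the cyclin-dependent kinase inhibitor p21, was higher at 0.93 (0.71 to 1.16) with regions at both gene ends, and ATM, a DNA damage kinase whose promoter region also serves NPAT, was lower at -1.07. The list was 0.071 above matched promoters, with 6 of 24 intervals above and 4 below. Apoptosis regulators were 0.036 above, with 4 of 20 above and 4 below, and BCL2, the anti-apoptotic gene, was at -1.20 and BIRC2 at -1.05. Cell cycle genes were 0.084 above, with E2F3 at -0.89 and RB1 at -0.81. Transcription elongation and pausing genes had a difference of -0.054, with LARP7, a component of the 7SK particle, at -1.23 and ELL2 at -1.01. Immediate early genes had a difference of -0.039, with NR4A2 at -1.04 and NR4A3 at -0.93, and myeloid transcription factors of 0.17, with CEBPD at -1.18 and regions at both gene ends. NF-kappaB and inflammatory genes had a difference of 0.17, with TRAF1 at -0.99, CXCL2 at -0.88 and IL10 at 0.84. Oxidative phosphorylation genes had a difference of -0.095, with TFAM at -0.89, and integrated stress genes of -0.11, with DNAJB9 at -1.16. Stem and progenitor genes were 0.38 above, with MEIS1 at -0.89 and HOPX at 0.88, and erythroid and megakaryocyte markers 0.44 above, with ITGA2B at 0.39. All of these lists lay inside the matched range. Members were named for their absolute fold, while the median of all promoters was -0.48 and their 5% quantile -1.02. E2F3, RB1, ELL2, NR4A3, TRAF1, CXCL2, TFAM and MEIS1 lay above that quantile, within the usual spread of promoters.

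The promoter with the highest fold was that of BLNK, the B cell linker adaptor, at chromosome 10 from 96271296 to 96271795, with 7 counts in the control and 71 in Day 1 (2.32, 1.29 to 3.77). It was followed by ATP1B2, a sodium pump subunit, at 2.25 (1.37 to 3.42), ANKRD65 at 1.99 (1.51 to 2.54) and the fructose transporter gene SLC2A5 at 1.98 (1.12 to 3.09). DPPA3 at 1.95, the ETS factor gene ETV7 at 1.93 with regions at both ends, MGST2 at 1.73, A4GALT at 1.71, SLC23A1 at 1.68 and LDLRAD2 at 1.67 completed the 10 highest. The lowest was the potassium channel gene KCNJ1, at chromosome 11 from 128866713 to 128867721, with 87 counts in the control and 43 in Day 1 (-1.93, -2.51 to -1.41). RASL11B at -1.73, the phosphatase gene PTPRK at -1.69, ZXDB at -1.67, ELAPOR2 at -1.62, TMEM185A at -1.59, FNIP2 at -1.58, PRKX at -1.55, NCKAP1 at -1.55 and the kinase gene BRAF at -1.55 followed.

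Away from gene ends, a region 12.5 kb from ADRA2B on chromosome 2 from 96100114 to 96100613 had 16 counts in the control and 391 in Day 1 (3.63, 2.96 to 4.50). Regions near TSNAX at 3.35, inside ADGRA3 at 3.13, near RREB1 at 3.06 and inside INSR, the insulin receptor gene, at 2.98 were next. A region inside TBC1D5, on chromosome 3 from 17401852 to 17402351 and 245 kb from the nearer gene end, had 142 counts in the control, 11 in Day 1 and 7 in Day 14. Its log2 fold of -4.50 (-5.66 to -3.74) in Day 1 was the lowest, followed by regions inside LRP8 at -2.85, PTPRN2 at -2.33 and HAUS7 at -2.32.

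Of 102334 regions, 9230 (9.02%) were at least 2-fold higher in Day 1 and 4324 (4.23%) at least 2-fold lower, against means of 636 and 254 from counting error alone. Higher regions made up 10.1% of regions outside promoters and 1.65% of promoter regions, and lower regions 3.99% and 5.88%. Promoter regions had a median log2 fold of -0.46, against 0.12 in other genic and 0.12 in intergenic regions, and their share of all counts was 38.7% in the control and 30.9% in Day 1. The fold was lowest at high counts: in the top decile of mean count, promoter regions had a median of -0.56, other genic regions of -0.26 and intergenic regions of -0.21. Of regions with at least a 2-fold difference, 68.1% were higher, against 84.4% with total counts, 98.7% with ribosomal protein promoters set to 0 and 49.2% after subtracting the intensity trend. With ribosomal protein promoters set to 0 the median promoter was at 0.23 in place of -0.48, so its sign depends on the scaling. Promoter regions minus other regions stood at -0.58, or -0.18 after subtracting the intensity trend.

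**Figure D1:**
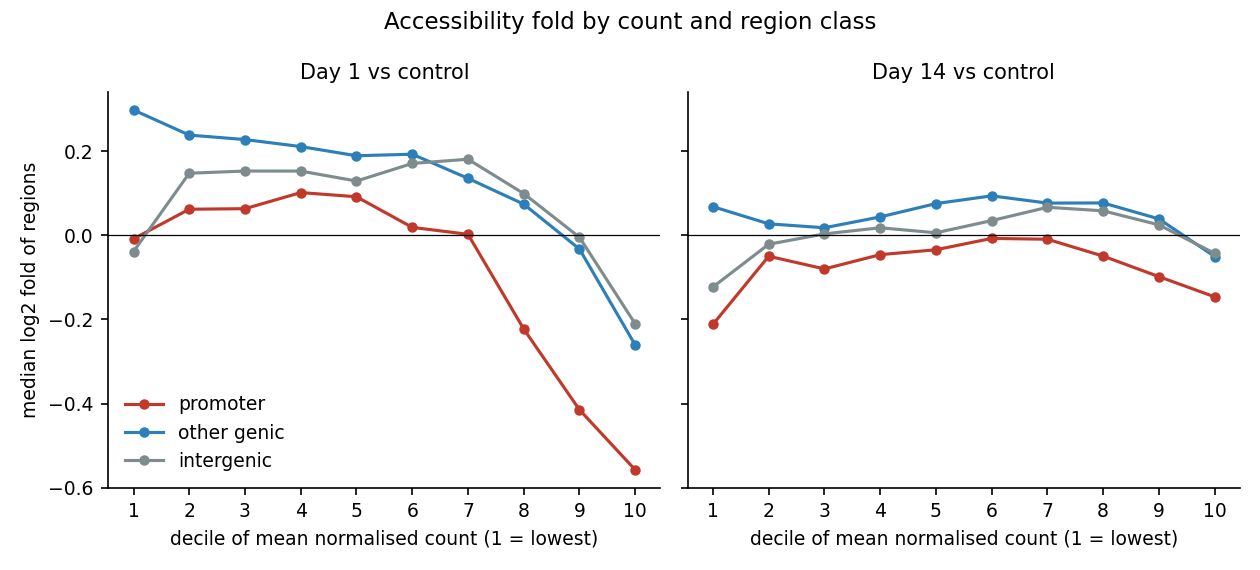
Median log2 fold of regions (y axis) in each decile of mean normalised count (x axis, no unit) for promoter, other genic and intergenic regions, in Day 1 and Day 14 against the control. Day 1 promoter regions reach -0.56 in the top decile, where Day 14 promoter regions stand at -0.15.

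The next comparison asks what differed from the control after the drug-free period. Promoters of neutrophil and lymphoid markers were above matched promoters in Day 14 as in Day 1, both against the same control library. Integrated stress and unfolded protein response genes were below them. The neutrophil list had a difference of 0.30, with 5 of 12 intervals above and 1 below; ITGAM was at 0.81 (0.30 to 1.37) and the formyl peptide receptor gene FPR1 at 0.57 (0.26 to 0.89), while the collagenase gene MMP8, with regions at both gene ends, was at -1.58 (-2.73 to -0.62) from 20 counts in the control and 15 in Day 14. The lymphoid list had a difference of 0.29, with 5 of 13 intervals above and 0 below, and EBF1 at 0.76 with regions at both gene ends, LCK at 0.66 and CD79A at 0.35 had the largest folds. The stress list had a difference of -0.14, with 5 of 15 intervals below and 0 above, led by ASNS, asparagine synthetase, at -0.61 (-1.02 to -0.20), PSAT1 at -0.44 and DDIT3 at -0.43.

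These 3 of 18 lists were outside the matched range, where chance gives 0.9. This comparison shares the control library with Day 1 vs control. Anything particular to the control library appears in both with the same sign, so lists and named promoters found in both are not independent findings. The neutrophil result changed sign to -0.019 when regions over the whole gene were counted and was 0.079, inside the range, with the nearest gene end within 50 kb; the lymphoid list was then at 0.15, also inside.

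The CDA promoter was also higher than in the control in Day 14, with 189 counts and a log2 fold of 1.26 (0.73 to 1.85), and SLC28A3, a concentrative nucleoside transporter, was at 0.86 (0.44 to 1.31). NME2 at -0.49 and ABCC4 at -0.47 were the lowest of the cytarabine list, which had a difference of -0.092 with 3 of 20 intervals above and 4 below. Among granule genes, MPO was at 0.92 (0.48 to 1.41) and the proteinase 3 gene PRTN3 at 0.83 (0.58 to 1.08), and the list was 0.10 above matched promoters. OASL at 1.51 (1.01 to 2.07) and IFIT2 at 1.03 (0.24 to 1.97) led the interferon list, which was 0.11 above with 3 of 19 intervals above and 2 below. BIRC3, an inhibitor of apoptosis, was at -1.90 (-2.85 to -1.12) from 33 counts in the control and 20 in Day 14, and the apoptosis list had a difference of -0.093. CDKN1A was at -0.052 (-0.29 to 0.19), and the p53 target list had a difference of -0.016, with TP53INP1 at -0.58 and TNFRSF10B, with regions at both gene ends, at -0.52. The progenitor gene HOPX was at 1.16 (0.36 to 2.13), with a list difference of -0.0053. Differences of the other lists were 0.061 for monocyte markers, 0.22 for erythroid markers, 0.10 for myeloid factors, 0.065 for immediate early genes, 0.015 for NF-kappaB genes, 0.014 for elongation genes, -0.018 for cell cycle genes, -0.041 for oxidative phosphorylation and -0.029 for ribosomal protein genes, all inside the matched range.

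**Figure D2:**
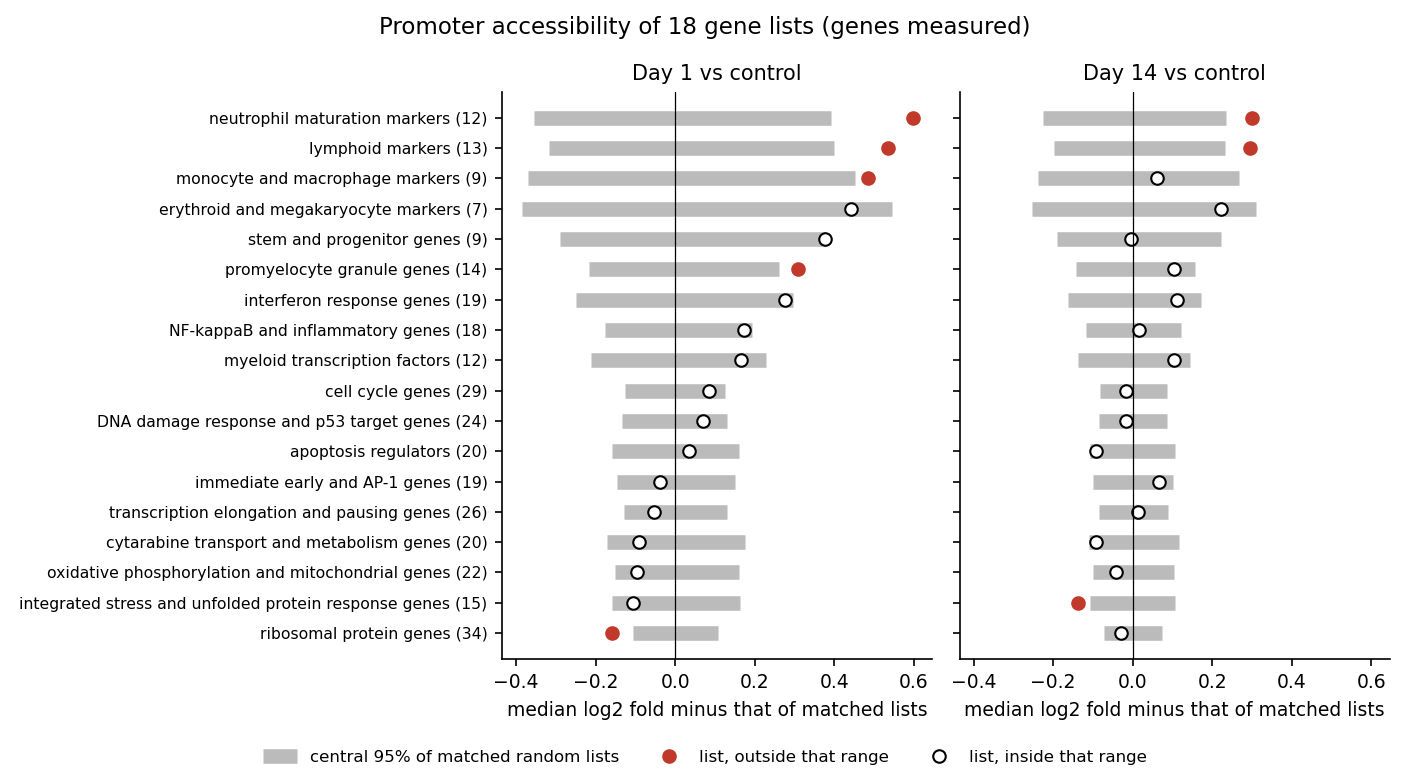
Median log2 fold of each gene list minus that of matched random lists (x axis, log2) for the 18 lists (y axis, genes measured in brackets), with grey bars for the central 95% of 10000 matched lists. Filled points, outside the bars, include neutrophil markers at 0.60 in Day 1 and 0.30 in Day 14.

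The 10 highest promoters in Day 14 were those of KLK11, a kallikrein with regions at both gene ends, at 2.23 (1.32 to 3.47), ETV7 at 2.13 (1.25 to 3.29), BLNK at 2.03 (1.00 to 3.48), ATP1B2 at 1.90, CGREF1 at 1.85, DPPA3 at 1.63, A4GALT at 1.52, OASL at 1.51, DEPDC4 at 1.35 and TNFSF11, the RANK ligand gene, at 1.31. The lowest were SPRR2D at -1.70 (-2.32 to -1.16), LHFPL6 at -1.37, the adenylate kinase gene AK5 at -1.36, FRRS1 at -1.30, ANKRD1 at -1.28, the shared promoter of ATPAF1 and TEX38, the latter with regions at both gene ends, at -1.25, PLAAT4 at -1.18, FBLIM1 at -1.16, the homeobox gene LHX1 at -1.14 and the shared promoter of SMC1B and RIBC2 at -1.10. Distal regions inside ITPR1 at 2.94 (1.81 to 4.73), near RREB1 at 2.89, inside CUX2 at 2.72, near RHCG at 2.64 and inside CD86 at 2.39 were the highest. The TBC1D5 region was the lowest here too at -5.34 (-6.93 to -4.51), against the same control count as in Day 1. Regions inside LRMDA at -1.68, PINX1 at -1.63, FEZ1 at -1.62 and CDCP1 at -1.58 followed.

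In Day 14, 4932 regions (4.82%) were at least 2-fold higher and 2761 (2.70%) at least 2-fold lower than in the control, against means of 722 and 234 from counting error alone. Promoter regions had a median log2 fold of -0.12 and held 36.2% of counts, against 38.7% in the control. With ribosomal protein promoters set to 0 the median promoter was at 0.050 in place of -0.12, so its sign depends on the scaling here too. Of the regions with at least a 2-fold difference, 64.1% were higher, against 83.0% with ribosomal protein promoters set to 0 and 53.7% after subtracting the intensity trend.

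**Figure D3:**
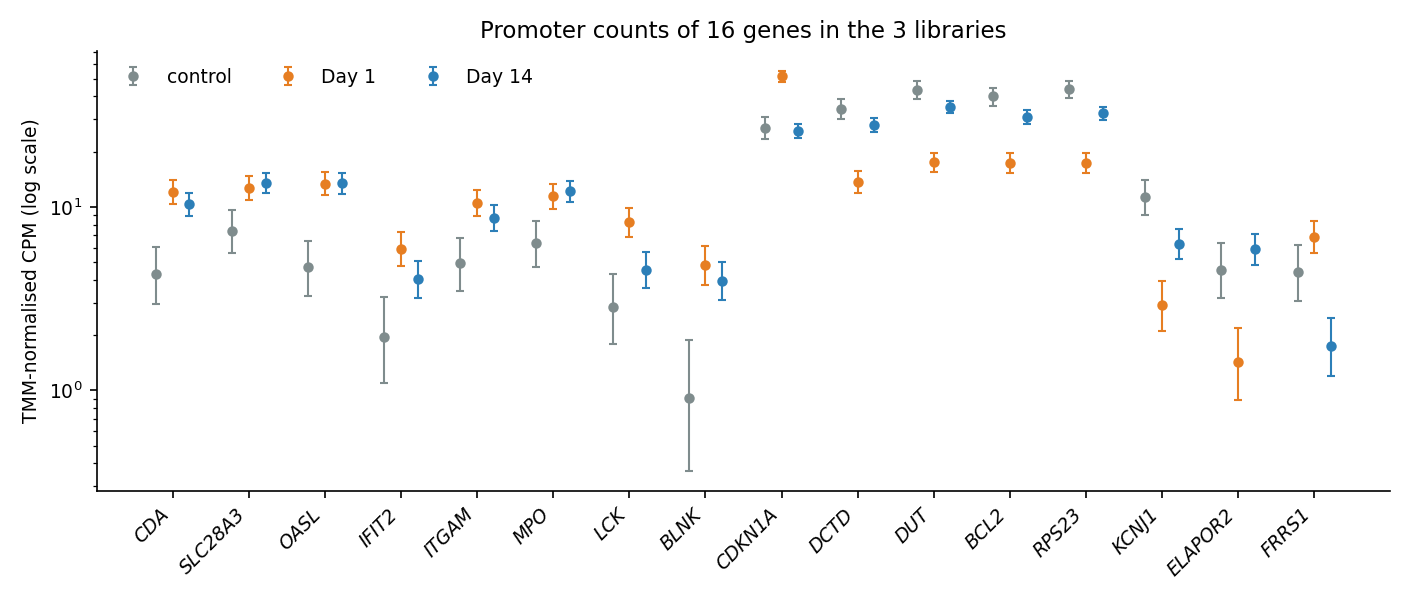
TMM-normalised promoter CPM (y axis, log scale) of 16 named genes (x axis) in the control, Day 1 and Day 14 libraries; points are single libraries and bars exact 95% Poisson intervals for counting error only. CDA stands at 4.29 in the control, 12.1 in Day 1 and 10.4 in Day 14, and CDKN1A at 26.9, 51.4 and 26.0.

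The last comparison asks which Day 1 levels were still present in Day 14. Relative to matched promoters, ribosomal protein genes were 0.16 higher in Day 14 than in Day 1, with 16 of 34 intervals above and 2 below, and RPL14 at 1.01 and RPS23 at 0.90 had the largest folds. Neutrophil markers were lower (difference -0.46, 9 of 12 intervals below and 0 above), with MMP8 at -1.41, MMP9 at -0.54 and CXCR2 at -0.51. Lymphoid markers had a difference of -0.37, with LCK at -0.84 (-1.27 to -0.44) and CD2 at -0.56 (-1.34 to 0.17). Granule genes had a difference of -0.24, with RNASE3 at -0.71 and regions at both ends and SRGN at -0.53, but PRTN3 at 0.71 and ELANE at 0.60. Interferon genes had a difference of -0.23, with OAS1 at -0.79 and OAS3 at -0.72 but the restriction factor gene MX2 at 0.81. DNA damage and p53 target genes had a difference of -0.11, with CDKN1A at -0.98 (-1.15 to -0.82) and the pro-apoptotic genes PMAIP1 at 0.76 and BBC3 at 0.75. Apoptosis regulators had a difference of -0.13, with BIRC3 at -0.85 and BCL2 at 0.84.

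These 7 of 18 lists were outside the matched range, where chance gives 0.9. This comparison shares the Day 1 library with Day 1 vs control. Anything particular to that library appears in both with opposite signs, so their lists and named promoters are not independent findings. The p53 target, apoptosis and interferon lists lay close to its edge, and subtracting the intensity trend brought the p53 list to -0.10 and the interferon list to -0.18, both inside it. With the nearest gene end within 50 kb the p53 list at -0.084, the apoptosis list at -0.11, the lymphoid list at -0.10 and the granule list at -0.070 were inside the range, as were with whole genes the p53 list at -0.030, the apoptosis list at -0.095, the granule list at -0.050, the lymphoid list at -0.20 and the interferon list at -0.17.

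In the cytarabine list, DCTD at 1.03 (0.79 to 1.27), DUT at 1.00 and CMPK1 at 0.84 were higher in Day 14 than in Day 1, and the list difference was 0.036. CCND2, a cyclin, at 0.97 and CDK6 at -0.74 led the cell cycle list (difference -0.061), FOSB at 0.95 and NR4A3 at 0.64 the immediate early list (-0.00032), LARP7 at 1.01 and MAX at 0.76 the elongation list (0.024), and SDHA at 0.79 the oxidative phosphorylation list (0.032). HSPH1 at 0.79 led the stress list (0.0051), MEIS1 at 0.63 the stem list (-0.061), MARCO at -0.56 the monocyte list (-0.32), TAL1 at 0.34 the erythroid list (-0.21), CEBPD at 0.69 the myeloid factors (-0.11) and IL6 at -0.71 the NF-kappaB genes (-0.11). These lists lay inside the matched range.

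The 10 promoters with the highest fold of Day 14 over Day 1 were ELAPOR2 at 1.98 (1.36 to 2.79), TMEM185A at 1.73, ZXDB at 1.62, RASL11B at 1.53, PRKX at 1.43, the corepressor gene TLE1 at 1.36, ISOC1 at 1.35, ZNF587B at 1.34, C8orf89 at 1.28 and MAOA, monoamine oxidase A, at 1.26. FRRS1 was lowest at -1.92 (-2.59 to -1.38), then ANKRD65 at -1.61, CRYBA1 at -1.46, ITGAE at -1.36, PLAAT4 at -1.35, EDN2 at -1.32, C10orf105 at -1.30, AGT at -1.28, CSF3, the granulocyte colony-stimulating factor gene, at -1.28 and the cytidine deaminase gene APOBEC3H at -1.24. A region inside LRP8 on chromosome 1 from 53320040 to 53320539 had 75 counts in the control, 19 in Day 1 and 157 in Day 14 (2.67, 2.05 to 3.51). Regions inside ORC1 at 2.15, NFE2L3 at 2.01, ENPEP at 1.90 and ERICH1 at 1.90 were next, and the region near ADRA2B was lowest at -2.41, followed by CRYBG2 at -2.28, MPRIP at -2.26, HDAC11 at -2.24 and TBCA at -2.22.

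In Day 14 vs Day 1, 2422 regions were at least 2-fold higher and 4394 lower, against 98.1 and 67.7 from counting error alone. Promoter regions had a median log2 fold of 0.34, but the median promoter turned from 0.35 to -0.22 with ribosomal protein promoters set to 0, and 35.5% of the regions with at least a 2-fold difference were higher. That share was 18.7% with total counts, 1.34% with ribosomal protein promoters set to 0 and 55.0% after subtracting the intensity trend.

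Of the 9230 regions at least 2-fold higher in Day 1, 3341 were also at least 2-fold higher in Day 14, where independent lists would share 445 and counting error alone gave 281. Of the 4324 lower regions, 831 were at least 2-fold lower in both, against 117 and 27. The simulated Day 1 lists were much smaller, with 675 higher and 261 lower regions, so the numbers shared cannot be set side by side as they stand. Both comparisons use the same control library, for which the independent values do not allow, so part of the excess may come from shared control counts. A Day 14 fold of the same sign was found in 92.7% of the higher and 90.4% of the lower regions of Day 1, but counting error alone, through the shared control, gave 99.9% and 97.3%, so these shares do not show a persistent difference. Across 102334 regions, which are not independent replicates, the folds had a Pearson r of 0.643, a Spearman rho of 0.595 and a covariance of 0.249, while counting error alone gave r of 0.690 and a covariance of 0.0683. The difference of the covariances, 0.181, does not include the counting error of the shared library but does include any real difference between that library and others. With the control counts split at random in 2 parts, each used for 1 comparison, r was 0.375 against 0.00454 for simulated counts. Then 2691 higher and 716 lower regions were shared, where independent lists would share 825 and 165. The same sign was found in 75.1% of the higher and 76.3% of the lower regions, against 52.3% and 48.4% for simulated counts. The split leaves the control library itself in common.

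Along the genome, 10 Mb windows differed by more than random sets of regions of the same size. Of 295 windows, 115 lay outside the central 95% in Day 1 vs control, 77 in Day 14 vs control and 129 in Day 14 vs Day 1, where chance gives 14.8. Window medians ranged from -0.49 to 0.27 in Day 1 and from -0.21 to 0.21 in Day 14. Chromosome 18 had a median log2 fold of 0.13 in Day 14 vs control, chromosome 19 of 0.066, chromosome 12 of 0.058 and chromosome 10 of -0.061. In Day 1 vs control, chromosome X was lowest at -0.0997, or -0.17 with the intensity trend subtracted, and chromosome 20 highest at 0.15. Chromosome X was at 0.13 in Day 14 vs Day 1. The promoters of ZXDB, TMEM185A, PRKX and MAOA named above lie on chromosome X, so part of their folds may reflect this shift.

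**Figure D4:**
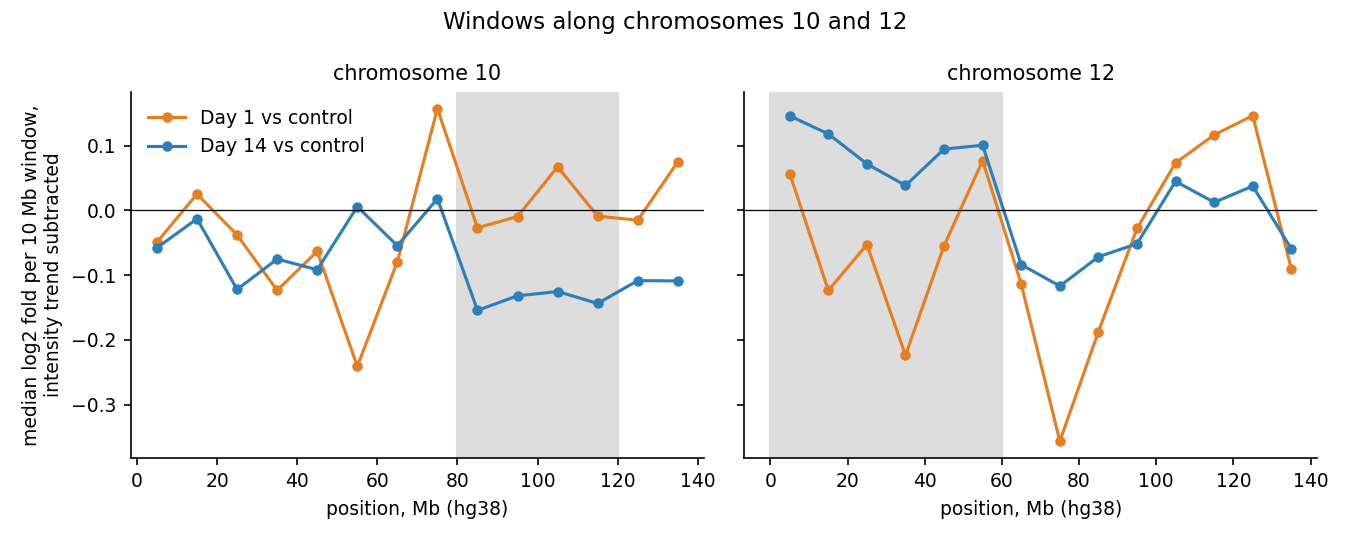
Median log2 fold per 10 Mb window (y axis, intensity trend subtracted) along chromosomes 10 and 12 (x axis, Mb) for Day 1 and Day 14 against the control, with runs of shifted Day 14 windows shaded. Day 14 medians on chromosome 10 from 80 to 120 Mb lie between -0.15 and -0.13, and the shaded run of chromosome 12 lies from 0 to 60 Mb.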

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

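The tests of explanations in this part were all chosen after the results they bear on had been seen. With 1 library per group, no search for an outlying sample was possible, and no difference between Day 1 and Day 14 was tested.

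A few named promoters and regions were singled out because their folds against the control had opposite signs in Day 1 and Day 14, with both counting intervals excluding 0. FRRS1 was at 0.63 in Day 1 and -1.30 in Day 14, and CRYBA1 at 0.64 and -0.82. ZNF587B was at -0.74 and 0.60, and the regions inside ORC1 at -1.54 and 0.61, inside NFE2L3 at -1.58 and 0.43 and inside ERICH1 at -1.26 and 0.64. The region near TBCA was at 1.28 and -0.94. The promoter of FOSB was at -0.70 and 0.25, and that of CCND2 at -0.77 and 0.20. These differences were not tested. Only named promoters, regions and list members were screened. FRRS1, CRYBA1, ZNF587B, ORC1, NFE2L3, ERICH1 and TBCA were among the highest or lowest of Day 14 vs Day 1. FOSB and CCND2 had the largest folds of their lists there. Such a choice favours opposite signs, and the counting intervals do not allow for it. Both intervals excluded 0 with opposite signs under each of the other 4 scalings for FRRS1 and CRYBA1 only. With ribosomal protein promoters set to 0 this was lost for ZNF587B, ERICH1, TBCA, FOSB and CCND2, and the Day 1 folds of ZNF587B, CCND2 and FOSB were then -0.031, -0.063 and 0.014. It was lost with the intensity trend subtracted for ORC1, NFE2L3, FOSB and CCND2, with median-of-ratios factors for ORC1, FOSB and CCND2, and with total counts for ZNF587B.

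Strong promoter regions were lower in Day 1 than other regions. Background reads spread evenly over the Day 1 library would move regions of equal count alike, but in the top decile promoters were lower than other regions of equal count by a median of -0.31 (bootstrap 95% interval -0.34 to -0.27), which argues against it as the whole cause. A bias of GC content or fragment length in the Day 1 library cannot be told apart from an effect of the drug without the sequence. A bias against GC-rich sequence would be expected to lower the fold of windows dense in regions, and the correlation across 294 windows between the log2 number of non-promoter regions and their median Day 1 fold with the intensity trend subtracted, was 0.685, the other way; density stands in for GC content only loosely and says nothing of fragment length, so this leaves the bias open (windows are not replicates). A biological effect of 1 day of cytarabine stays open and untested, because it was seen in a single library.

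Promoters of granule, neutrophil, monocyte and lymphoid genes were above matched promoters in Day 1; erythroid and megakaryocyte markers at 0.44 lay inside the matched range, and stem and progenitor genes at 0.38 lay just inside it, at the 97.4 percentile, and outside at 0.34 with the intensity trend subtracted. Granulocytic maturation as the whole cause would leave lymphoid markers inside that range. Their list lay at the 99.5 percentile, or inside the range at 0.26 with the nearest gene end within 50 kb. That cannot decide the question, because the lymphoid list is part of the pattern to be explained. Random lists were also not matched on GC content, so a GC or fragment length bias of the Day 1 library stays open here too. A shift of tissue-restricted promoters in general was tested with 45 olfactory receptor, keratin and kallikrein genes, the last of these picked after KLK11 had been seen; they lay at the 94.0 percentile, inside the range, which leaves it undecided. Olfactory receptors at -0.23 and keratins at 0.37 from matched promoters were inside their ranges, and the 7 kallikreins at 0.69 were above theirs. In Day 14, neutrophil and lymphoid markers were also above matched promoters. The families together at 0.24, keratins at 0.38 and kallikreins at 0.78 then lay above their ranges and olfactory receptors at -0.011 inside. Random lists were not matched on chromosome. KLK11 lies on chromosome 19, where 867 genes other than zinc finger (ZNF) genes were 0.12 above matched promoters in Day 14. A shift of tissue-restricted promoters stays open, as do a few mature cells within the sorted G0/G1 gate, which were not tested for.

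Blocks of adjacent 10 Mb windows were shifted in Day 14. Found on every other region as runs of at least 4 windows with medians of at least 0.08 in size, there were 2 blocks, where shuffled windows gave a mean of 0.37 and gave as many in 4 of 100 shuffles. In the regions held out, chromosome 10 from 80 to 120 Mb had a Day 14 shift of -0.14 in promoters and -0.10 in other regions, and chromosome 12 from 0 to 60 Mb of 0.12 and 0.086. A change in copy number or clone mixture was tested by whether promoters and other regions both shift with the block, as they did in 2 of 2 blocks. The held-out regions lie in the same windows and libraries, so a regional shift of any cause would reappear, and this cannot decide the cause. Shuffling also removes any likeness of neighbouring windows. Chromosomes 18 and 19 had Day 14 medians of 0.086 and 0.096 with the trend subtracted but gave no block. The regional trend of the Day 1 library is argued against for chromosome 10, where Day 1 shifts were -0.0028 in promoters and 0.021 in other regions, and for other regions of chromosome 12 at -0.0089, but for promoters of chromosome 12 it cannot be told apart, since their Day 1 shift was 0.10 (bootstrap 95% interval 0.039 to 0.19). A regional effect on chromatin would give the same result, and the sequencing lane of Day 14 cannot be told apart from its group.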

How the results depend on the processing

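Counts of regions with at least a 2-fold difference, the class difference of promoters from other regions and the gene lists were recomputed under the other scalings, pseudocount and filters, the correlation of folds with split control counts, a mean of at least 50 and the trend, and named items with total counts, the trend and the pseudocount. Thinning to the control's depth, counting whole genes, the class alternatives and the trend for the correlation were added after the data were seen. All 6 region counts stayed within 1.5 times under median-of-ratios factors, a pseudocount of 5 and thinning. With ribosomal protein promoters set to 0 they became 36864 higher and 483 lower in Day 1, 7732 and 1589 in Day 14, and 303 and 22292 in Day 14 vs Day 1. With a mean of at least 50, which leaves fewer regions, they were 3109 and 1658, 1324 and 243, and 785 and 956. With no filter, which adds regions of low count, 6907 were lower in Day 1, 5368 lower in Day 14 and 3805 higher in Day 14 vs Day 1. Total counts gave 2470 lower in Day 1 and 1515 higher in Day 14 vs Day 1, and the subtracted trend 5882 higher in Day 1 and 2831 lower in Day 14 vs Day 1. Promoters minus other regions moved with the subtracted trend to -0.18 in Day 1, -0.062 in Day 14 and 0.12 in Day 14 vs Day 1, from -0.58, -0.17 and 0.40. The correlation of 0.643 was 0.375 with the control counts split, which removes shared counts and also lowers the control depth of each comparison, 0.635 with a mean of at least 50 and 0.639 with the trend subtracted. Total counts, median-of-ratios factors and ribosomal scaling shift all promoters by about the same amount, which cancels in a difference from matched promoters, so they do not test the lists. Of 324 list values under the other alternatives, 285 kept their side of the matched range. Changes of sign were not counted for lists inside the range both times. Among lists outside the range in the main analysis, 1 changed sign: neutrophil markers in Day 14 at -0.019 with whole genes. With the nearest gene end within 50 kb, calls ended for Day 1 granule (0.14) and lymphoid lists (0.26), for Day 14 neutrophil (0.079) and lymphoid lists (0.15), and for Day 14 vs Day 1 p53 (-0.084), apoptosis (-0.11), lymphoid (-0.10) and granule lists (-0.070). Lists that came to lie outside the range were NF-kappaB (0.099) and cytarabine genes (-0.13) in Day 14, stress genes (-0.20) in Day 1, and monocyte (-0.29), stem (-0.24) and elongation genes (0.14) in Day 14 vs Day 1. With whole genes, calls ended for Day 1 granule (0.093) and for Day 14 vs Day 1 p53 (-0.030), apoptosis (-0.095), interferon (-0.17), lymphoid (-0.20) and granule lists (-0.050), and arose for immediate early genes (-0.26 in Day 1, 0.21 in Day 14 vs Day 1), stress genes (-0.21, 0.15), monocyte markers (0.18 in Day 14, -0.24 in Day 14 vs Day 1) and stem genes (-0.20 in Day 14 vs Day 1). With the trend subtracted, calls ended for p53 (-0.10) and interferon genes (-0.18) in Day 14 vs Day 1 and monocyte markers (0.32) in Day 1, and arose in Day 1 for interferon (0.36), myeloid factors (0.22) and stem genes (0.34). A mean of at least 50 ended p53 (-0.10) and gave calls for interferon genes in Day 1 (0.41) and monocyte markers in Day 14 vs Day 1 (-0.37), and no filter ended p53 (-0.11) and gave interferon in Day 1 (0.38). No list call changed with a pseudocount of 5, and none of the highest and lowest promoters and regions changed sign with total counts, the trend or the pseudocount, though the trend moved PRKX from -1.55 to -1.07 in Day 1 and from 1.43 to 1.06 in Day 14 vs Day 1, and C10orf105 from -1.30 to -1.69 there. Of 216 values of list members with the largest folds, 104 left their counting interval with the trend and 10 with total counts. With the trend 3 changed sign: CD4 (0.29 to -0.12) and TFRC (0.28 to -0.13) in Day 14 vs Day 1 and CX3CR1 (-0.18 to 0.014) in Day 1. CD4 has regions at both gene ends. Apart from filter size, the cause was not tested. GC correction, GC-matched lists and motif analyses were not run, as no genome sequence was used here. No paired analysis was possible because each group has 1 library. Control depth limits low-count regions most: 245 regions had 0 counts there, against 79 in Day 1 and 10 in Day 14.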

Other observations

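The screen of gene families described here was chosen after the data were seen. Promoters were grouped by the letters that open the gene symbol, which gave 88 families of at least 15 measured genes, and each was set against 10000 matched random lists. In Day 1 vs control 6 families lay above the matched range and 2 below it, where chance gives 2.2 on each side. Day 14 vs control had 3 and 1, close to chance, and Day 14 vs Day 1 had 7 and 4. Genes whose symbols start with CD and a digit, mostly leukocyte surface proteins, had the largest family difference, 0.42 over 64 genes. The 49 of them on no fixed list had a difference of 0.41, and in Day 14 of 0.12. Examples picked for their size are CD207 at 1.69 (0.30 to 3.8) from 4 counts in the control, CD300LD at 1.33 (0.63 to 2.15), CD48 at 0.87 (0.38 to 1.41), CD300LB at 0.85 (0.37 to 1.37) and CD244 at 0.77 (0.53 to 1.03). Interleukin and interleukin receptor genes (symbols starting with IL and a digit) had a difference of 0.34 over 43 genes in Day 1 and 0.074, inside the range, in Day 14. Chemokine genes of the CCL family had a difference of 0.39 in Day 1 over 16 genes. The other 3 above the range in Day 1 were ZSCAN at 0.31, LOC at 0.13 and SLC at 0.060. In Day 14 vs Day 1 the families below the range were CCL at -0.29, CD at -0.27, IL at -0.22 and LOC at -0.074, and those above were OR at 0.31, DNAJC at 0.13, RPL and RPS at 0.12 each, POLR at 0.11, RBM at 0.097 and ZNF at 0.072. These differences share the Day 1 library with the ones against the control. The families RPL and RPS, which hold the ribosomal protein genes on and off the fixed list, had differences of -0.15 and -0.15 in Day 1 vs control and were the 2 below the range.

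Zinc finger genes of the ZNF family were 0.068 above matched promoters in Day 14 vs control over 354 genes, with CD at 0.16 and TRAPPC at 0.12 also above the range there and TTC at -0.13 below it. The excess was on chromosome 19, where 153 ZNF genes were 0.16 above and 867 other genes 0.12 above, while 201 ZNF genes on other chromosomes had a difference of -0.0047, inside the range. On chromosome 19, ZNF320 at 1.69 (0.75 to 2.94), ZNF615 at 1.27 (0.62 to 2.04), ZNF28 at 0.79 (0.38 to 1.24) and ZNF614 at 0.75 (0.39 to 1.12) had high Day 14 folds and were picked for their size. Chromosome 19 genes other than ZNF were 0.12 above matched promoters in Day 1 also.

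The region inside TBC1D5, with 142 counts in the control against 11 in Day 1 and 7 in Day 14, was 22.6-fold lower in Day 1 and 40.5-fold lower in Day 14 after the pseudocount was added. Both folds rest on the same control count, and Day 14 vs Day 1 was at -0.84 (-2.57 to 0.54). A signal particular to the control library cannot be told apart from a loss in both drug groups. The next lowest distal regions were, on the same scale, 7.19-fold lower in Day 1 and 3.21-fold lower in Day 14. Unplaced contigs, left out of the comparisons, had a normalised CPM of 1088 in the control, 537 in Day 1 and 737 in Day 14.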
